A study of Mus musculus with 8 samples.

How the data were processed

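RNA was extracted from the prefrontal cortex of C57BL6/J mice, per the labels, after injection of AAV9 carrying either GFP or a hairpin RNA. Per the labels' protocols, the groups are biological duplicates and total RNA was purified with a DNase step. Stranded libraries were made from 1 µg of RNA with ribosomal RNA depletion and sequenced on an Illumina HiSeq, per the labels' protocols. The design text of the series speaks of 3 knockdown and 2 control mice, while 2 libraries per group were analysed here. The titles of the knockdown samples name Adnp and Pogz, while the treatment label of both groups names a hairpin against ASH1L. Groups were taken from the titles. The second Pogz library carries the number 3 in its column name, per the file headers, and was used as the library its title names.

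The deposited values are raw read counts per gene symbol. Per the submitters' processing notes, the authors used STAR, featureCounts and DESeq2 with build mm10, whereas the labels' protocols name Cutadapt and TopHat2 against RefSeq transcripts. Versions, the strand setting and the treatment of reads that match several places are not given in the sources used here. Values of genes with near-identical copies (histocompatibility genes, C4a, ribosomal protein genes), of overlapping genes and of antisense genes are therefore uncertain. In each library 25 identifiers had been turned into calendar serial numbers, as a spreadsheet does, and 2 identifiers were blank. These were left out of library sizes and tests, the date entries holding 0.306% to 0.337% of the counts of a library. The remaining 23393 gene symbols were used. Coordinates come from the GRCm38.p6 annotation, the same assembly as mm10, in which 16147 of the 17415 tested symbols were found.

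Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group with a minimum count of 10, which left 17415. Libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion was fitted to all 8 libraries with 1 mean per group. It had 4 residual degrees of freedom and a common biological coefficient of variation of 0.171. The contrasts were shAdnp against its GFP controls, shPogz against its GFP controls, the difference between these responses, and the Pogz-set against the Adnp-set GFP controls. The average effect of knockdown came from a model with terms for set and knockdown. P-values were adjusted over all genes by Benjamini-Hochberg at 0.05. CPM values are TMM-scaled, and log2 fold changes carry the standard error of the model. With 2 libraries per group, p-values rest on a spread shared across genes and groups. Total counts in named genes ranged from 27501722 to 69002749 per library. Every pair of libraries differed by more than counting noise (chi-square per degree of freedom from 15.0 to 394, over genes with at least 10 counts), so each was counted as a separate library.

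A total of 41 gene lists was fixed before the data were examined, and the 39 with at least 3 tested members were tested. The mitochondrial genome list (0 tested members) and the red blood cell list (1 tested member, Alas2) were left out. The functional lists were microglial activation, complement, interferon-stimulated genes, antigen presentation, cytokines and NF-kB targets, reactive astrocytes, glutamate postsynapse, presynapse, GABA receptors, ion channels, activity genes, ribosomal proteins, oxidative phosphorylation, heat shock, the unfolded protein response, p53 targets, glucocorticoid-induced genes, clock genes, cholesterol synthesis, cell cycle, chromatin partners, autism risk genes and sex-linked genes. The cell type lists were microglia, blood leukocytes, astrocytes, oligodendrocytes and their precursors, endothelium, mural cells, meninges, choroid plexus, ependyma, striatum, olfactory bulb, excitatory neurons, upper and deep cortical layers and interneurons. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 39 lists. Camera with an estimated correlation and fry stand beside it. Members were also counted as passing when adjusted over the list alone.

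The rule for the genes named was written at the same time as the lists. It takes Adnp, Pogz and Ash1l, and up to 8 genes each way with the largest change among genes past the adjusted p, of which there were 0. It also takes the 4 members with the smallest p in the direction of each list that passed camera, and at most 2 of any other list. The text names only a part of the genes this rule gives, a restriction added after the data were seen, and genes outside it are said to be chosen after their values were seen. Results of some single genes that the rule gives are not reported here.

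The alternatives set at that time were DESeq2 1.42.0, limma-voom, RLE and upper quartile scaling, no low-count filter, a minimum of 1 CPM in 2 libraries, other thresholds, only the 4 libraries compared, the replicate number as a block, and each replicate left out in turn. DESeq2 with each replicate left out and the omission of 2 libraries together were added after the data were seen. The tests were checked on simulated counts for the 17415 genes, drawn from their means, dispersions and the library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. In the Adnp comparison edgeR recovered 66% of the 2-fold and 86% of the 4-fold changes, and DESeq2 72% and 89%. In the Pogz comparison edgeR recovered 59% and 87%, and DESeq2 69% and 90%. For the difference of responses edgeR recovered 21% and 71%, and for the average effect 78% and 91%. False calls made up 11.4% of edgeR's calls in the Adnp comparison, 8.48% in the Pogz comparison, 5.10% for the difference and 6.95% for the average, against 20.8%, 25%, 24.7% and 18.6% of DESeq2's. With no gene changed in the Adnp design, edgeR called 1 gene and DESeq2 26. A simulated rise of the microglia list passed camera with the preset correlation in all 4 simulations, with no other list called, while its adjusted p with an estimated correlation ranged from 0.00633 to 0.0975. The simulation gives each gene independent noise and so leaves out the joint movement of genes between real replicates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.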

Results

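The data were RNA sequencing read counts per gene from the prefrontal cortex of mice that had received an adeno-associated virus of serotype 9 (AAV9). There were 8 libraries in 4 groups of 2. A group labelled by its titles as Adnp knockdown by short hairpin RNA, called shAdnp here, was set against its own controls injected with a virus expressing green fluorescent protein (GFP), and a group labelled as Pogz knockdown (shPogz) against a separate pair of GFP controls. Adnp and Pogz encode zinc finger proteins that act in chromatin, and the series title asks whether the 2 risk genes of neurodevelopmental disorders act through a common mechanism. Total counts in named genes were 62999525 and 65104567 in the Adnp-set GFP controls, 63024070 and 55641435 in shAdnp, 27501722 and 69002749 in the Pogz-set GFP controls, and 41560029 and 35164558 in shPogz (replicates 1 and 2 in each group). The ribosomal RNA precursor gene Rn45s took 7.62% of the counts in shAdnp replicate 1 against 0.134% to 0.740% in the other 7 libraries (named after its values were seen). Of 23393 genes, 17415 were tested. On a multidimensional scaling plot of the 8 libraries, the first axis held 52.3% of the spread and ran from Adnp-set GFP replicate 1 at -2.47 to shPogz replicate 2 at 2.15, with the other 6 libraries between -0.66 and 0.80.

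The targeted genes were examined first, because the treatment label of both knockdown groups names another gene, Ash1l, while the sample titles name Adnp and Pogz. Adnp (chromosome 2, 168180965 to 168207112, mm10) stood at 137 and 111 CPM (counts scaled to the TMM-normalised library size) in its GFP controls and at 87.2 and 118 CPM in shAdnp. Its log2 fold change was -0.27 (SE 0.19; edgeR adjusted p = 0.768), and shAdnp replicate 2 lay above a control. Without shAdnp replicate 1 the value was -0.05, without shAdnp replicate 2 it was -0.50, without Adnp-set GFP replicate 1 it was -0.10 and without GFP replicate 2 it was -0.41. Pogz (chromosome 3, 94822989 to 94883577) stood at 54.4 and 53.1 CPM in its controls and at 49.0 and 37.3 CPM in shPogz, both below the controls, with a log2 fold change of -0.32 (SE 0.16; edgeR adjusted p = 0.667). That value was -0.13 without shPogz replicate 2 and -0.49 without shPogz replicate 1. Ash1l (chromosome 3, 88950414 to 89079375), a histone methyltransferase gene, differed by -0.10 (SE 0.14) in the Adnp set and by 0.11 (SE 0.14) in the Pogz set. In the opposite sets, Pogz differed by -0.12 (SE 0.16) in shAdnp and Adnp by -0.10 (SE 0.19) in shPogz. None of the 3 genes passed the test adjusted over all genes in either set. By that test a lower level of the targeted transcript was not detected in these whole-tissue libraries. Adjustment over all genes is strict for genes chosen beforehand, and given the standard errors a modest fall is not excluded. Group names below are those of the labels.

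**Figure D1:**
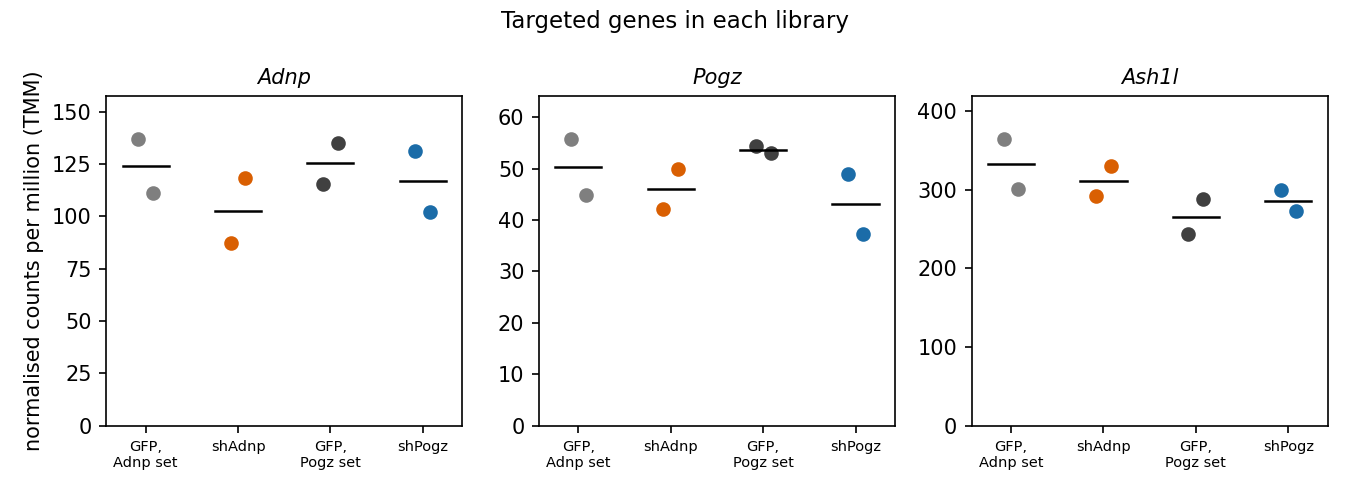
Normalised counts (CPM, TMM scaling) of Adnp, Pogz and Ash1l in each library (points) of the 4 groups, with the mean of each group of 2 as a line. Adnp is at 87.2 and 118 in shAdnp against 137 and 111 in its controls, and Pogz at 49.0 and 37.3 in shPogz against 54.4 and 53.1.

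The comparison of shAdnp with its GFP controls asks which genes respond to the Adnp virus. Genes of microglia, the resident macrophages of the brain, were higher in the libraries labelled shAdnp. All 20 measured microglial markers lay above 0, with a median log2 fold change of 1.01, and 19 of the 20 passed when adjusted over the list alone (0 when adjusted over all genes). The camera calls for the microglia, microglial activation and complement lists were lost with an estimated correlation (adjusted p = 0.268 with an estimated correlation for each). The integrin Itgam was at 29.8 and 38.4 CPM in the controls and 79.3 and 64.4 CPM in shAdnp (log2 fold change 1.07, SE 0.19). Csf1r, the receptor for the growth factor on which microglia depend, was at 118 and 155 against 288 and 232 CPM (0.93, SE 0.19), and Ly86 at 9.84 and 16.1 against 59.1 and 41.2 CPM (1.95, SE 0.37). Genes of microglial activation and phagocytosis were higher by a median of 1.54, with 28 of 28 members passing when adjusted over the list alone and 0 over all genes. They included the endotoxin co-receptor Cd14 (1.59, SE 0.34), lipoprotein lipase Lpl (1.16, SE 0.25) and osteopontin Spp1 (1.65, SE 0.36). Complement genes had a median of 1.63, with 6 of 13 passing over the list alone and 0 over all genes. The receptor C3ar1 stood at 3.68 and 4.49 against 21.6 and 11.7 CPM, and C1qa at 48.1 and 96.4 against 340 and 204 CPM.

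Reactive astrocyte genes were higher by a median of 1.14 in shAdnp, with 13 of 18 passing when adjusted over the list alone (0 over all genes), among them the hyaluronan receptor Cd44 (5.49 and 7.02 against 17.5 and 14.3 CPM). The camera calls for the reactive astrocyte, meningeal and cytokine lists were lost with an estimated correlation (adjusted p = 0.268, 0.268 and 0.412 with an estimated correlation). Of 26 cytokine, chemokine and NF-kB genes, 11 passed over the list alone and 0 over all genes (median 1.24), including Il1a, which encodes interleukin 1 alpha (1.06 and 1.10 against 4.85 and 3.47 CPM), and the inflammasome sensor Nlrp3 (1.72, SE 0.35). Markers of meningeal and perivascular fibroblasts were higher too: 12 of 15 passed over the list alone and 0 over all genes, with a median of 0.83. Among them, the growth factor gene Igf2 rose from 20.4 and 19.7 CPM to 37.3 and 37.4 CPM by the test within the list, and Igfbp2, which encodes a binding protein of insulin-like growth factors, from 25.3 and 29.5 CPM to 66.0 and 47.1 CPM. The 15 cell cycle genes had a median of 0.94, and the replication helicase gene Mcm3 alone passed over the list alone (1.26, SE 0.30; for the list, adjusted p = 0.547 with an estimated correlation). Antigen presentation (median 1.70), blood leukocyte (1.76) and interferon-stimulated genes (1.18) were higher as lists, with 0 members passing either way. These calls too were lost, with adjusted p = 0.547 with an estimated correlation for antigen presentation and 0.554 for the other lists. The controls themselves stood apart in these genes, B2m being at 80.9 CPM in GFP replicate 1 and 217 CPM in GFP replicate 2, against 405 and 415 CPM in shAdnp. Smaller positive medians were found for mural cells (0.34), oligodendrocyte precursors (0.21), neuronal activity genes (0.26) and ribosomal proteins (0.08), with adjusted p from 0.268 to 0.767 with an estimated correlation.

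Lists with a negative median in shAdnp were small in size, and none of the 7 that passed camera did so with an estimated correlation (adjusted p from 0.547 to 0.767 with an estimated correlation). Cholesterol synthesis genes had a median of -0.28 with all 15 members below 0. Deep cortical layer markers stood at -0.36 and inhibitory GABA receptor genes at -0.20. The median was -0.15 for oxidative phosphorylation genes (71 of 78 members below 0, the complex I gene Ndufv2 being at 120 and 119 against 95.3 and 87.1 CPM). Voltage-gated ion channels, glutamate postsynapse genes and autism risk genes stood at -0.10, -0.09 and -0.08. No member of these 7 lists passed over the list alone or over all genes. Lists that did not pass in this comparison, with adjusted p from 0.0848 to 0.961, were astrocytes (median 0.03; the water channel gene Aqp4 passed over the list alone), oligodendrocytes (-0.07), endothelium (0.12), choroid plexus (0.28), ependyma (0.10), striatum (-0.12), olfactory bulb (0.03; Eomes and Kctd12 passed over the list alone), excitatory neurons (-0.09), upper layers (0.19), interneurons (-0.02), presynapse (-0.08), heat shock (-0.07), the unfolded protein response (0.03), p53 targets (0.16), glucocorticoid-induced genes (-0.01), clock genes (0.08), chromatin partners of ADNP and POGZ (0.01) and sex-linked genes (-0.02). The median and the mean differed in sign for interneuron and chromatin partner genes, and also for glucocorticoid-induced and sex-linked genes.

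Gene by gene, 0 of 17415 genes passed edgeR's quasi-likelihood test for shAdnp at an adjusted p of 0.05, the smallest adjusted p being 0.295. At an unadjusted p under 0.05 there were 1456 genes, 1161 higher and 295 lower. Exact p-values with no change would give 870.75 on average. Regrouping the 4 libraries of this set, with the Pogz set grouped in each way, gave from 117 to 1035 genes. DESeq2 called 420 genes (416 higher, 4 lower) and limma-voom 0. Of the 416, 52 were among the 172 measured members of 8 immune and reactive glial lists (those of microglia, their activation, complement, interferon, antigen presentation, cytokines, reactive astrocytes and blood leukocytes). By camera with a preset correlation, 21 of 39 lists passed (14 higher, 7 lower), with adjusted p of 1.72e-35 for microglial activation, 1.34e-29 for microglia, 1.06e-22 for reactive astrocytes, 5.32e-18 for cytokines, 1.30e-17 for meninges and 2.91e-14 for complement. No list passed with an estimated correlation between genes: adjusted p = 0.268 with an estimated correlation for each of these lists except cytokines (0.412), and 0.268 to 0.767 over the 21. The DESeq2 count was 7 without Adnp-set GFP replicate 1, 154 (68 higher, 86 lower) without shAdnp replicate 1 and 226 without shAdnp replicate 2. The members passing over the list alone fell to 0 for microglial activation without either GFP replicate 1 or shAdnp replicate 1, and from 19 to 4 and 7 for microglia. Some list medians moved less: without Adnp-set GFP replicate 1 they were 1.21 for microglial activation, 0.95 for microglia and 0.88 for meninges. Those of other lists fell further, to 0.80 for complement, 0.99 for antigen presentation, 0.92 for blood leukocytes and 0.65 for interferon-stimulated genes. Without GFP replicate 2 the last 3 were 3.23, 4.10 and 2.22.

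For the smaller lists, the calls for oligodendrocyte precursors, activity genes, ribosomal proteins, glutamate postsynapse, ion channels and autism risk genes ended without Adnp-set GFP replicate 1 and also without shAdnp replicate 1. The deep layer call ended without shAdnp replicate 2, where the median was -0.0028, against -0.99 without shAdnp replicate 1. The cholesterol median stayed between -0.32 and -0.24 with any of the 4 libraries left out and passed camera each time, although adjusted p = 0.547 with an estimated correlation. For oxidative phosphorylation the median was -0.08 without GFP replicate 2 or without shAdnp replicate 2, -0.21 without GFP replicate 1 and -0.20 without shAdnp replicate 1, with adjusted p = 0.554 with an estimated correlation. GABA receptor genes gave -0.13 without shAdnp replicate 1 (adjusted p = 0.564 with an estimated correlation).

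**Figure D2:**
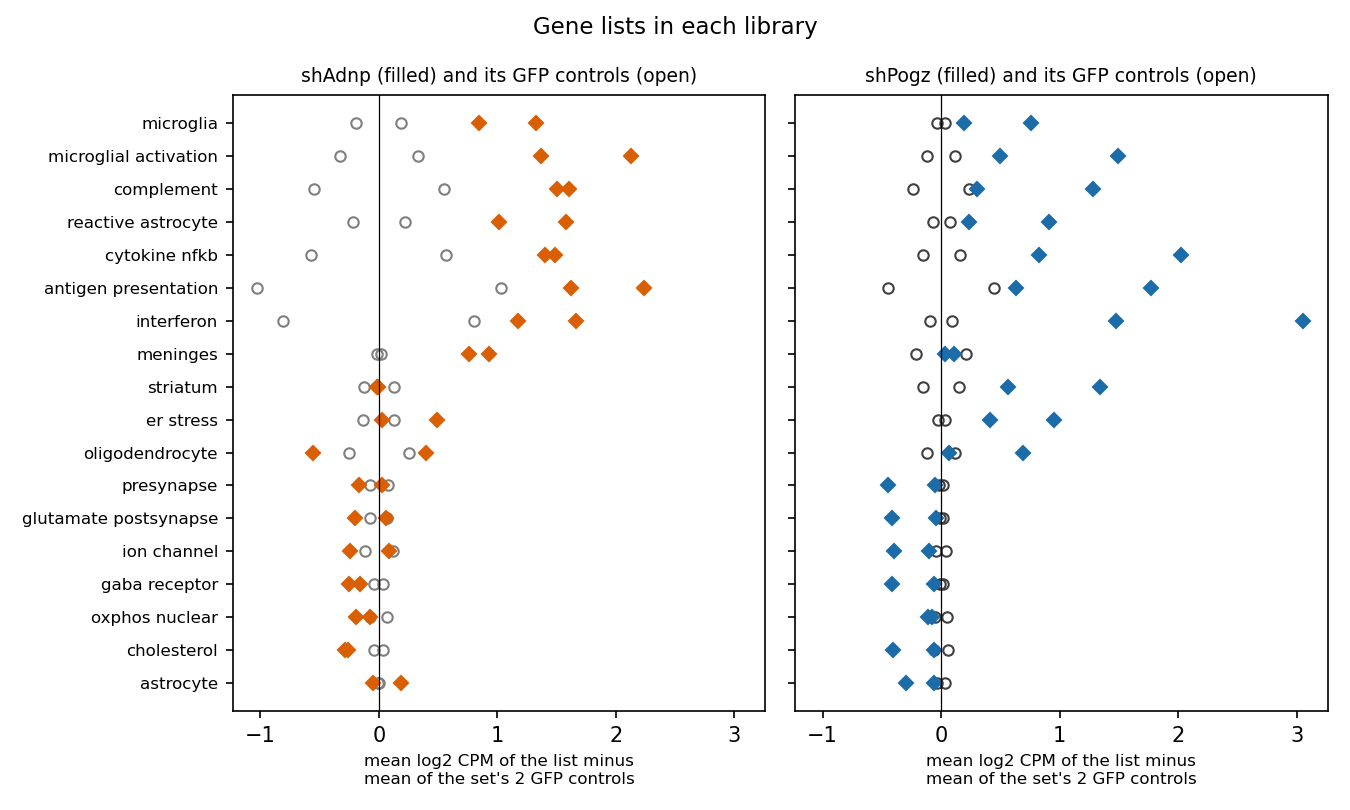
Mean log2 CPM of 18 of the fixed gene lists in each library, minus the mean of the 2 GFP controls of its set (open circles, GFP controls; filled diamonds, knockdown libraries; the lists shown were chosen after their values were seen). Microglial activation genes are at 2.13 and 1.37 in shAdnp and at 0.50 and 1.49 in shPogz, and interferon genes at 1.48 and 3.06 in shPogz.

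The libraries labelled shPogz were compared with their own GFP controls to ask the same of the Pogz virus. Interferon-stimulated genes were the list with the highest median, 2.43, with 28 of 28 members above 0, and 19 passed when adjusted over the list alone (0 over all genes). The camera calls of this list and of the cytokine list were lost with an estimated correlation (adjusted p = 0.506 with an estimated correlation for each). The antiviral gene Rsad2 (viperin) was at 9.41 and 7.22 CPM in the controls and 54.2 and 203 CPM in shPogz (log2 fold change 3.96, SE 0.82). Oas2, an antiviral sensor of double-stranded RNA, was at 2.94 and 1.86 against 6.41 and 19.8 CPM (2.47, SE 0.63), and Ifi35 at 6.12 and 7.18 against 15.3 and 34.1 CPM (1.89, SE 0.45). Of 26 cytokine, chemokine and NF-kB genes (median 1.44), 6 passed over the list alone and 0 over all genes. The inflammatory caspase Casp4 stood at 2.19 and 2.56 against 5.66 and 14.9 CPM, and the chemokine Ccl12 at 2.97 and 2.69 against 6.01 and 14.9 CPM. Ccl3 (0.78 and 0.70 against 1.85 and 7.20 CPM) and Ccl4 (0.28 and 0.43 against 1.64 and 8.49 CPM) also passed within the list, but they overlap in the annotation and their separate values are uncertain.

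Genes of the unfolded protein response had a median of 0.35 in shPogz with all 15 above 0, and 2 members passed over the list alone and 0 over all genes (adjusted p = 0.506 with an estimated correlation for this list and for the striatal list). The members were Chac1, a glutathione-degrading enzyme induced by the transcription factor ATF4 (chromosome 2, 119351242 to 119354326; 6.44 and 6.91 against 11.9 and 24.0 CPM; 1.42, SE 0.28), and the pseudokinase Trib3 (0.57 and 0.57 against 1.59 and 4.35 CPM). Markers of striatal medium spiny neurons, cells of a region that lies next to the frontal cortex, had a median of 0.69 with 14 of 14 above 0. Syndig1l (0.50 and 0.99 against 1.92 and 4.03 CPM) and the dopamine receptor Drd2 (0.88 and 0.95 against 1.73 and 4.06 CPM) passed over the list alone, 0 over all genes. Among abundant members of that list, Adcy5 moved by 0.02 and Penk by 0.05, but Ppp1r1b by 0.26 and Pde10a by 0.60. These examples were chosen after their values were seen. Microglial activation genes had a median of 1.00 and microglial markers one of 0.35, with 0 passing over the list alone or over all genes; Spp1 was at 4.24 and 5.32 against 8.54 and 14.1 CPM. The other lists with a positive median were antigen presentation (1.23), blood leukocytes (1.03), complement (0.95), cell cycle (0.72), reactive astrocytes (0.67), oligodendrocytes (0.45) and ribosomal proteins (0.09), with 0 members passing either way. These lists and the microglial ones had adjusted p from 0.506 to 0.666 with an estimated correlation.

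Neuronal genes were lower as lists in shPogz, by small amounts and with 0 members passing over the list alone or over all genes. These calls were lost with an estimated correlation (adjusted p from 0.506 to 0.618 with an estimated correlation) and also by camera without shPogz replicate 2. The median was -0.27 for presynaptic genes (22 of 22 members below 0) and -0.27 for voltage-gated ion channels (24 of 24), -0.26 for GABA receptors, -0.24 for upper layer markers, -0.22 for glutamate postsynapse genes, -0.17 for interneurons, -0.16 for excitatory neurons and -0.15 for autism risk genes. The metabotropic GABA receptor gene Gabbr1 was at 834 and 782 CPM in the controls and 713 and 513 CPM in shPogz. Clock genes (-0.23), cholesterol synthesis (-0.22), astrocytes (-0.17) and oxidative phosphorylation (-0.08) were lower as well, with adjusted p from 0.506 to 0.669 with an estimated correlation. Lists that did not pass, with adjusted p from 0.0550 to 0.969, were oligodendrocyte precursors (median 0.05), endothelium (-0.09), mural cells (-0.17), meninges (0.07), choroid plexus (-0.25), ependyma (0.30), olfactory bulb (0.07), deep layers (-0.07), activity genes (0.08), heat shock (0.11), p53 targets (0.10), glucocorticoid-induced genes (-0.05), chromatin partners (-0.06) and sex-linked genes (0.10).

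In the test of single genes, 0 of 17415 genes passed edgeR for shPogz, with a smallest adjusted p of 0.667 (Chac1). At an unadjusted p under 0.05 there were 1167 genes, 706 higher and 461 lower. DESeq2 called 100 genes, all higher, of which 18 were among the 172 members of the 8 immune and reactive glial lists, and limma-voom called 0. By camera with a preset correlation, 25 of 39 lists passed (13 higher, 12 lower), with adjusted p of 4.83e-36 for interferon, 1.19e-17 for cytokines, 1.39e-15 for microglial activation, 5.50e-11 for the unfolded protein response, 2.32e-10 for striatum and 1.77e-06 for presynapse. None passed with an estimated correlation: adjusted p = 0.506 with an estimated correlation for each of these 6 lists, and 0.506 to 0.669 over the 25. Much of the comparison rested on shPogz replicate 2, without which 11 lists passed (10 higher, 1 lower) and DESeq2 called 2 genes. The median was then 1.39 for interferon, 0.61 for cytokines, 0.37 for microglial activation, 0.10 for microglia, 0.32 for striatum, 0.21 for the unfolded protein response and -0.09 for presynapse. Every negative list except oxidative phosphorylation lost its call. Without shPogz replicate 1, edgeR called 153 genes (139 higher, 14 lower) and DESeq2 991, interferon stood at 3.07 and microglial activation at 1.47. DESeq2 called 2 genes without Pogz-set GFP replicate 1, and without either Pogz-set control the members passing over the list alone went from 19 to 0 for interferon and from 6 to 0 for cytokines.

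Whether the 2 responses differed was tested as the Pogz response minus the Adnp response. By edgeR 0 genes passed, DESeq2 called 2 genes and limma-voom 0. At an unadjusted p under 0.05 there were 612 genes (192 higher, 420 lower), fewer than the 870.75 that exact p-values with no change would give on average. The 2 genes called by DESeq2, both lower in the Pogz response, were Igf2 (of the meningeal list) and Lama1, which encodes a laminin chain of basement membranes and was chosen after its values were seen. By camera 20 of 39 lists differed. Meningeal markers were lower in the Pogz response (median -0.83, 7 of 15 passing over the list alone and 0 over all genes; adjusted p = 4.28e-12, and adjusted p = 0.287 with an estimated correlation), as were microglia (-0.62) and microglial activation (-0.66). Interferon (1.08) and striatum (0.77) were higher in the Pogz response. No list passed with an estimated correlation, with adjusted p = 0.705 with an estimated correlation for microglia, microglial activation and interferon and adjusted p = 0.551 with an estimated correlation for striatum. By fry, which tests a list on its own, mural cells passed (adjusted p = 0.0492).

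The common response, named in the series title, was measured as the average effect of knockdown over both sets. By edgeR 0 genes passed, with a smallest adjusted p of 0.142 (Clec5a, a myeloid surface receptor gene, chosen after its values were seen), while 2171 had an unadjusted p under 0.05 (1540 higher, 631 lower). DESeq2 called 711 (697 higher, 14 lower) and limma-voom 0. Adjusted over the list alone, 27 of 28 microglial activation genes (median 1.24), 27 of 28 interferon genes (1.85), 19 of 26 cytokine genes (1.38), 18 of 20 microglial markers (0.70), 16 of 18 reactive astrocyte genes (0.96) and 10 of 13 complement genes (1.32) were higher, against 0 of each over all genes. Each of these lists passed camera, with adjusted p from 3.28e-35 to 5.86e-12, and adjusted p = 0.330 with an estimated correlation for each. Without shPogz replicate 1 edgeR called 556 genes, and without both Adnp-set GFP replicate 1 and shPogz replicate 2, a choice made after the data were seen, it called 2.

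**Figure D3:**
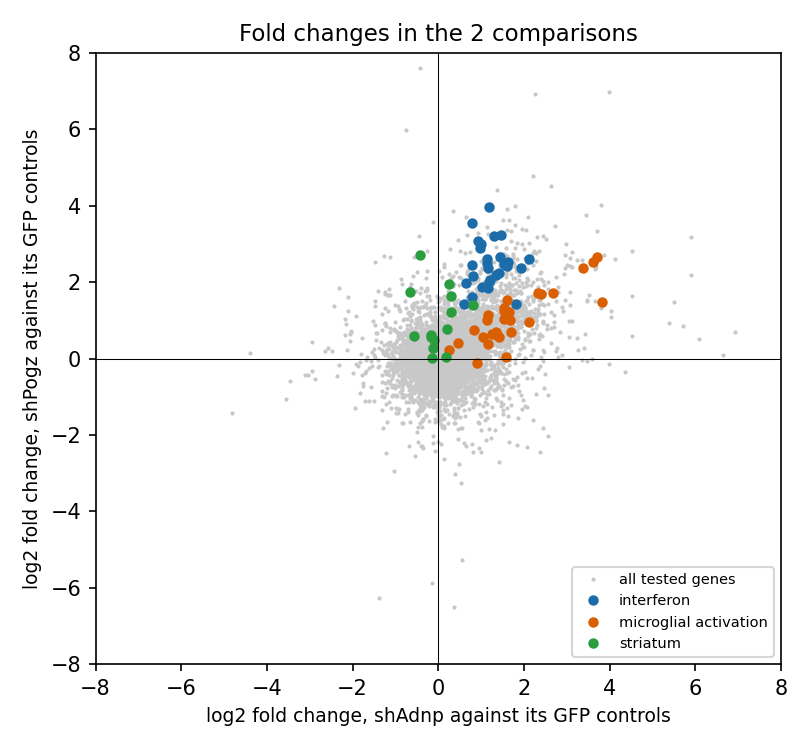
Log2 fold changes of the 17415 tested genes in shAdnp (x axis) and in shPogz (y axis), each against its own GFP controls, with 3 of the fixed lists marked; the lists were chosen after their values were seen. The 28 interferon genes and all but 1 of the 28 microglial activation genes lie above 0 on both axes, and the 14 striatal markers lie above 0 for shPogz.

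Genes with an unadjusted p under 0.05 were shared between the 2 comparisons more often than independent lists would give for higher genes (274 in both, 47.1 for independent lists; Fisher's exact test, p = 4.58e-144, genes not being independent). This was not so for lower genes (5, against 7.81 for independent lists; exact p = 0.460), and 12 genes went in opposite directions (42.7 for independent lists). No gene was called in both by edgeR at an adjusted p of 0.05, while DESeq2 called 42 in both, all higher (2.39 for independent lists). Among those 42 were Spp1, C3ar1, Casp4, Axl, Ccl3, Ccl4 and Ccl12, all members of the immune lists. Across genes, which are not independent replicates, the log2 fold changes of the comparisons correlated with a Pearson r of 0.42 and a Spearman rho of 0.25. Regrouping the 4 libraries of each set in all 9 combinations of splits gave r from -0.30 to 0.37 for the 8 others. For rho the range was -0.29 to 0.26. The sign of a regrouped value is arbitrary, because either side can be taken as the knockdown. By size the real grouping had the highest r but not the highest rho, which both -0.29 and 0.26 exceeded. The 9 combinations cannot give a share under 0.05. The correlation was 0.13 without shPogz replicate 2 and 0.25 without Adnp-set GFP replicate 1. Without both of these libraries, an omission chosen after the data were seen, it was 0.05. With a minimum of 1 CPM in 2 libraries it was 0.62, and with each comparison fitted on its own 4 libraries 0.53.

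The 2 pairs of GFP controls, which carry the same label, were compared to show the background difference between the sets. Wdfy1 (chromosome 1, 79702262 to 79776143), the 1 gene called by edgeR (adjusted p = 0.0112), was higher in the Pogz-set controls, at 64.7 and 65.6 CPM against 20.8 and 18.1 CPM, and was named after its values were seen. At an unadjusted p under 0.05 there were 1280 genes, DESeq2 called 73 and limma-voom 1. Between these controls, microglial activation genes differed by a median of 0.70 (camera adjusted p = 2.06e-07; adjusted p = 0.687 with an estimated correlation), microglia by 0.55 (adjusted p = 0.643 with an estimated correlation) and blood leukocyte genes by 1.99 (adjusted p = 0.643 with an estimated correlation), all higher in the Pogz set. No member of these 3 lists passed over the list alone or over all genes. The call for Wdfy1 ended without Adnp-set GFP replicate 1, where edgeR called 0 genes, and without Pogz-set GFP replicate 1, where it called 1 gene that was lower in the Pogz set. By edgeR 6 genes were called without Pogz-set GFP replicate 2 and 2 without Adnp-set GFP replicate 2.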

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

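All tests of explanations in this part were chosen after the results were seen. Of the 39 gene lists, 20 differed between the Pogz and the Adnp response in a camera test of the difference itself with a preset correlation. None passed with an estimated correlation (adjusted p from 0.287 to 0.807 with an estimated correlation). The values are medians, over a list's genes, of the Pogz response minus the Adnp response on the log2 scale. Lower in the Pogz response were complement (-0.83), meninges (-0.83), microglial activation (-0.66), microglia (-0.62), reactive astrocytes (-0.53), mural cells (-0.51), upper cortical layers (-0.43), activity genes (-0.26), astrocytes (-0.23), interneurons (-0.23), presynapse (-0.20), clock genes (-0.20) and endothelium (-0.19). Higher were heat shock (0.062), oxidative phosphorylation (0.069), deep cortical layers (0.36), the unfolded protein response (0.40), oligodendrocytes (0.48), striatum (0.77) and interferon-stimulated genes (1.08).

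Immune and reactive glial lists had positive medians in the libraries labelled as knockdown in both sets. In the Adnp comparison the middle of the 8 list medians was 0.93 at the lowest with 1 library left out (1.39 with all), which argues against a single library as the whole cause, and meningeal tissue is argued against in the Pogz comparison, where its markers had a median of 0.070. Open explanations are 1 library in the Pogz comparison, where the middle median was 0.38 without shPogz replicate 2 (1.02 with all), and meningeal tissue in the Adnp comparison, where its median was 0.83. Chance cannot be excluded, since 3 of the 35 splits of the 8 libraries gave at least as many genes at an unadjusted p under 0.05 as the real one (2171, highest other 3174); the 2 others move libraries across the sets unevenly, and among the 18 splits with 2 libraries of each set on each side the real one was the highest (highest other 1818), but 18 splits are too few for a share under 0.05. The split with 3174 genes called 121 genes at an adjusted p of 0.05. It put Adnp-set GFP replicate 1, both Pogz-set controls and shPogz replicate 1 against the rest. Within the sets it thus parted Adnp-set GFP replicate 1 and shPogz replicate 2 from the others. These libraries lay at the ends of the first scaling axis (-2.47 and 2.15). An effect of the knockdowns stays open. It was not tested apart from the viruses, because every knockdown library carries the hairpin virus and every control the GFP virus.

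Striatal markers had a median of 0.69 in shPogz. It was 0.32 without shPogz replicate 2, so 1 library may account for much of its size. Neighbouring striatum in the dissected tissue should raise the markers together, and 11 of the 14 lay above both controls in both shPogz libraries. Of the abundant markers, chosen after their values were seen, Adcy5 (0.02) and Penk (0.05) barely moved, while Ppp1r1b (0.26) and Pde10a (0.60) were higher. Whether the level of Adcy5 and Penk in the controls could hide a small share of striatal RNA was not tested, because no striatal library was among the samples. Pde10a stood above Penk in both Pogz-set controls and still rose more, while Adcy5 stood above Pde10a. Striatal tissue and a change within cortical cells cannot be told apart here, because the count decides neither way.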

How the results depend on the processing

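DESeq2 with 1 replicate left out and the omission of 2 libraries together were chosen after the results were seen. Summary counts were run with RLE, upper quartile scaling, limma-voom, a minimum of 1 CPM, a fold-change minimum and only the 4 libraries compared. None of the counts run moved by over 1.5 times. The gene counts were 0 by edgeR, or 1 between the controls, so their staying there shows little. Of these settings, lists were run only with RLE, and no list call moved. Named genes were run with RLE and with the 4 libraries compared (244 of the 246 results). None was called by edgeR before or after. DESeq2 called 420 genes for shAdnp, 100 for shPogz, 2 for the difference, 73 between the GFP controls and 711 on average, with 42 shared, where edgeR called 0 in each but 1 between the controls. It also called 40 of the 246 named gene results. An unadjusted p in both comparisons gave 279 shared genes. An FDR of 0.10 and the lack of a filter each gave 6 genes between the controls. An estimated correlation and fry each left 0 lists in both comparisons (21 and 25 by camera). Depth limits genes with few counts, some of which passed the low-count filter. The cause of these differences was not tested.

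With each replicate left out, the lone library of a group is assumed to vary like the others. EdgeR then called 0 to 8 genes for shAdnp, 0 to 153 for shPogz, 0 to 4 for the difference, 0 to 556 on average and 0 to 6 between the controls, with 0 shared. Without shAdnp replicate 1 there were 8 for shAdnp (all lower) and 4 for the difference, and without shPogz replicate 1 there were 153 for shPogz and 556 on average. Lists numbered 16 to 27 for shAdnp and 11 to 26 for shPogz, the correlation across genes was 0.13 to 0.39, Adnp in shAdnp stood at -0.50 to -0.05 and Pogz in shPogz at -0.49 to -0.13. For shAdnp, DESeq2 called 7 and 591 genes without GFP replicate 1 and 2, and 154 and 226 without shAdnp replicate 1 and 2. For shPogz it called 2 and 114 without GFP replicate 1 and 2, and 991 and 2 without shPogz replicate 1 and 2. Without both Adnp-set GFP replicate 1 and shPogz replicate 2 the average effect had 2 genes and the correlation was 0.047. The cause was not tested.

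Some log2 values changed sign with 1 library left out. In shAdnp, without GFP replicate 1 Pogz was 0.056 and Ash1l 0.062, and the lowest values, without GFP replicate 2, were -0.27 and -0.23. Uty ranged from -0.091 to 0.0024. Without shAdnp replicate 1 Gjb1 was -0.39, Trp53inp1 -0.00087, Pogz 0.0057 and Ash1l 0.0025, against 0.89 and 0.73 for Gjb1 and Trp53inp1 without shAdnp replicate 2. Opalin was 0.17 and Dnaja1 0.025 without shAdnp replicate 2, and -0.64 and -0.40 without replicate 1. Of the list medians, glutamate postsynapse ranged from -0.18 to 0.082, ion channels from -0.24 to 0.10 and ribosomal proteins from -0.0031 to 0.22. These 3 changed sign without shAdnp replicate 1, and ion channels also without GFP replicate 1 (0.055). Activity genes stayed positive, from 0.0076 (without GFP replicate 1) to 0.55, the test pointing down at 0.0076. Deep layers ranged from -0.99 to -0.0028, the test pointing up at -0.0028. In shPogz, Adnp was 0.053 without GFP replicate 2 and 0.067 without shPogz replicate 2, and -0.26 without shPogz replicate 1. Ak7 was -0.10 and ribosomal proteins -0.016 without shPogz replicate 2, and 1.26 and 0.25 without replicate 1. The cause was not tested.

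By the labels, the replicate numbers pair no samples. Deviations of same-numbered libraries from their group means correlated at -0.0085 in the Adnp set and 0.047 in the Pogz set. With the replicate number as a block, edgeR called 175 genes for shAdnp, 31 for shPogz and 405 on average, all higher, and 0 for the difference, while 4 of the 46 list calls were lost.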

Other observations

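The tests in this part were chosen after the results were seen, and so were the comparison and the genes it names. With all 4 libraries of each set in the model of set and knockdown, 11 genes differed between the sets by edgeR, 8 higher and 3 lower in the Pogz set (2145 at an unadjusted p under 0.05, 258 by DESeq2 and 10 by limma-voom). Wdfy1, on chromosome 1, stood at 66.5 ± 8.49 CPM in the Pogz set and 19.9 ± 1.22 CPM in the Adnp set (SD, n = 4; edgeR adjusted p = 9.20e-05). Nnt, the mitochondrial transhydrogenase gene on chromosome 13, stood at 44.5 ± 5.11 against 27.3 ± 1.99 CPM (edgeR adjusted p = 0.0347). Lower in the Pogz set were the ribosomal protein genes Rps2 (35.9 ± 1.71 against 68.6 ± 6.34 CPM) and Rps18 (26.8 ± 3.24 against 46.9 ± 3.85 CPM) and the splicing gene Rnps1 (35.2 ± 3.41 against 58.0 ± 3.63 CPM). The histocompatibility genes H2-T10 (19.9 ± 3.91 against 2.14 ± 1.23 CPM) and H2-Q10 (3.32 ± 1.89 against 0.116 ± 0.0788 CPM) were higher in the Pogz set. So were C4a (like H2-T10 annotated as a transcribed pseudogene), Gm6034, Gm11127 and C920025E04Rik, for the last of which no coordinates were matched. Apart from Wdfy1, Nnt and Rnps1, the values of these genes are uncertain where near-identical copies or overlapping genes share reads.

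A candidate explanation for these genes is a different genetic background of the mice in the 2 sets. Of the 10 called genes with coordinates, 8 lie on chromosome 17 between 24414646 and 36121444 (mm10), a chromosome that holds 4.94% of the tested genes with coordinates (Fisher's exact test, p = 1.42e-09, counting neighbouring genes as independent), as an inherited segment there would give. Immune content of the samples is argued against as the whole cause, because between the 2 Adnp-set controls, which differed by 2.06 in the antigen presentation list, the 11 genes differed by a median of 0.13 in the direction of the set difference, although H2-T10 (1.30) and Gm6034 (1.45) moved with it. Of the 35 splits of the libraries, 2, counting the real one, called at least 11 genes. That count cannot decide on chance for these 11 genes, because it takes any called gene. The place of 8 of the 10 genes on chromosome 17 argues against chance for those 8, counting neighbouring genes as independent. The other split called 325 genes. Within the controls it parted Adnp-set GFP replicate 1 from the rest, and within the knockdown libraries shPogz replicate 2. These libraries lay at the ends of the first scaling axis (-2.47 and 2.15). Genotypes, which would test the hypothesis, were not analysed here.

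All 8 libraries held RNA of the Y-linked gene Ddx3y, at 89.9 to 130 CPM, and little Xist, at 0.14 to 0.79 CPM.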
